A study of Mus musculus with 12 samples.

How the data were processed

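RNA-seq libraries of mouse embryonic stem cells were analysed from 4 groups of 3 libraries: WT and eIF2α A/A knock-in (KI) cells, each after 6 days in LIF/2i or in LIF. Per the labels' protocols, cells were washed with cycloheximide and lysed, RNA was taken from the supernatant of the spun lysate with Trizol, ribosomal RNA was depleted, and the RNA was fragmented and carried through the steps of a ribosome profiling library. RNA in the pellet was not measured. Ribosome profiling data are not analysed here.

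The values are raw counts per gene deposited by the authors in 1 table, with no normalization. The submitters' processing notes name cutadapt 3.4, Bowtie 1.3.0 and UMI-tools 1.0.1 without saying what each was used for. The genome build, the annotation, the counting tool and the treatment of strand, molecular identifiers and reads with several matches are not given in the sources used here. Genes that share sequence with copies elsewhere, such as ribosomal protein, mitochondrial and Rhox genes, or that overlap another gene, are therefore uncertain. Per the file headers, counts cover the coding sequence of 1 transcript per gene, so reads in untranslated regions were not counted. All values were whole numbers. Of 22416 genes, 4483 had no count in any library. Transcript identifiers were matched to GENCODE release M21 (GRCm38), where 22155 were found and 21766 had the same symbol; coordinates are from that annotation.

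Replicates of a group were compared by a chi-square test of their counts over genes with at least 20 counts. WT LIF replicates 1 and 3 agreed within sampling noise and were counted as 1 sample with their mean, which left 11 samples. The design fixed beforehand had assumed 12. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

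Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 13239. Counts were scaled by TMM (factors 0.945 to 1.04) and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust) with 1 mean per group over all samples. Each contrast was tested two-sided by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.234. Standard errors of log2 fold changes were taken from the F statistic. Fold changes of genes near 0 counts depend on the prior count, and 3 counts were taken as the floor of a library. Levels are TMM-scaled CPM, except Y-linked CPM, which use library totals.

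Of 31 gene lists fixed before the data were examined, 29 had at least 4 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. They were ATF4 targets, tRNA synthetases, eIF2 machinery, ER chaperones, NRF2, p53, ERK, Wnt, Nodal and TGFβ, BMP and LIF/STAT3 targets, naive, core and formative pluripotency, DNA methylation machinery, germline and imprinted genes, primitive endoderm, trophectoderm, mesendoderm, neuroectoderm and fibroblast markers, glycolysis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, lysosome, cholesterol synthesis and G2/M genes. A list of 2-cell-like genes had too few tested members, and a list of X- and Y-linked genes was read by level only. Members were also counted with p-values adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list moves on balance.

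The genes named were chosen by a rule fixed before the data were examined. It took, per comparison, up to 6 higher and 6 lower called genes with the largest fold change, a mean of at least 5 CPM and no overlap between groups, leaving out predicted symbols, clone names and pseudogenes. It added 2 called members of each of the 6 called lists with the smallest p, and the panel Eif2s1, Nanog, Esrrb, Klf4, Pou5f1, Fgf5, Dnmt3b, Atf4, Asns and Trib3. Fgf5 was under the count filter. Other genes named as list members, as library facts or as the shared genotype genes were chosen after their values were seen.

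The groups share replicate numbers. Deviations from the group means were correlated between same-numbered samples. In KI samples across media the correlations were 0.5, 0.37 and 0.22 for replicates 1, 2 and 3. The highest with another number were -0.22, 0.081 and 0.21. The numbers therefore match KI replicates 1 and 2 across media, from the data and not from the labels, and replicate 3 hardly. In the other comparisons at least 1 pair was under 0.1, although WT replicate 2 had 0.13 across media.

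Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library totals alone, no filter, a minimum count of 30, a test against a 1.5-fold change, only the groups compared, the replicate number as a block, and leaving out each library. That block was fitted over all 12 libraries, with the agreeing pair counted separately. Alternatives chosen after seeing the data were 12 libraries counted separately, the sum of the agreeing pair, a block within KI cells, KI replicates 2 and 3 alone, and leaving out both agreeing libraries. Where leaving out a library or splitting controls left 1 sample in a group, it was assumed to vary like the other groups.

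The fit was tested on simulated counts drawn from the real means, totals and dispersions with known changes added to some genes. Of genes changed 4-fold, 69.7% were recovered for KI against WT in LIF/2i (12929 genes), 68.2% in LIF (12928), 64.6% for the medium in WT (12915), 76.9% in KI (12921) and 55.6% for the interaction (12920). Of genes changed 2-fold, 36.9%, 26.2%, 21.2%, 39.4% and 9.09% were recovered in the same order. Calls of unchanged genes were 9 of 83, 3 of 65, 6 of 65, 4 of 89 and 3 of 45, so the share of false calls passed 0.05 in 3 of the 5. At these depths and sample numbers a gene that was not called is not shown to be unchanged. A simulated list of shifted genes was called in each of the 5 simulations and 0 of 50 unshifted lists in each. Genes were drawn independently, so the simulated lists cannot show false list calls that correlation between genes would cause. Real lists were correlated, with an estimate of 0.584 for p53 targets in KI against WT in LIF/2i. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.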

Results

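RNA was sequenced from mouse embryonic stem cells of 2 genotypes in 2 media. The wild-type (WT) cells carried normal eIF2α, the translation initiation factor subunit encoded by Eif2s1. The knock-in (KI) cells were homozygous for the A allele, in which the serine that stress kinases phosphorylate is replaced by alanine. Phosphorylation of eIF2α lowers general protein synthesis and raises translation of Atf4, a transcription factor that turns on amino acid synthesis and transport genes. Cells were held for 6 days in serum-free medium with leukaemia inhibitory factor (LIF) alone or with LIF plus PD0325901 and CHIR99021, inhibitors of MEK and GSK3 (LIF/2i). The study asked how eIF2α phosphorylation controls the naive state of pluripotency. Each of the 4 groups had 3 libraries, 12 in all.

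The WT libraries in LIF/2i held 6701358, 7738055 and 3234713 counts and those in LIF 6092300, 6376905 and 6333407. The KI libraries in LIF/2i held 9713857, 8052510 and 6305690 counts and those in LIF 2835135, 4609908 and 2307219. Low genes were therefore measured least precisely in KI cells in LIF, where 3 counts equalled up to 1.3 CPM (counts scaled to a common library total). WT LIF replicates 1 and 3 differed by less than the sampling noise, with a chi-square per degree of freedom of 0.858 over 12373 genes. KI LIF replicates 2 and 3, the closest pair above that noise, had 2.61. The other pairs of the same group had 9.46 to 40.2. Only the WT LIF pair was counted as 1 sample. WT in LIF therefore had n = 2 and each other group n = 3.

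Eif2s1 itself (transcript ENSMUST00000071230, chromosome 12, 78861819 to 78887010, GRCm38) was measured in every sample. Its level was 25.7 ± 2.32 CPM (SD, n = 3) in WT LIF/2i, 30.5 ± 2.87 (SD, n = 2) in WT LIF, 44.2 ± 13.3 (SD, n = 3) in KI LIF/2i and 37 ± 1 (SD, n = 3) in KI LIF. The KI to WT difference was not past the threshold in LIF/2i (log2 fold change 0.78 ± 0.21 (SE), adjusted p = 0.079) or LIF (0.28 ± 0.24, adjusted p = 0.744). Without KI LIF/2i replicate 1 the LIF/2i difference was called (0.96, adjusted p = 0.0134), with the KI libraries at 31, 44.1 and 57.6 CPM. Counts per gene carry no information on the point mutation, so they do not check the genotype labels.

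Libraries also differed in Y-linked transcripts, both within and between genotypes. Ddx3y, Eif2s3y, Uty and Kdm5d summed to 261 and 259 CPM in WT LIF/2i replicates 1 and 3 but to 44.9 CPM in replicate 2. In WT LIF the sums were 165, 77.7 and 156 CPM. KI replicate 1 had 41.6 CPM in LIF/2i and 36.7 CPM in LIF, while KI replicates 2 and 3 had 1.86 and 1.43 CPM in LIF/2i and 2.17 and 3.9 CPM in LIF. The highest KI sum, 41.6 CPM, thus lay under the lowest WT sum, 44.9 CPM. Comparisons of KI with WT therefore cannot separate the mutation from whatever else differs between the WT and KI libraries.

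**Figure D1:**
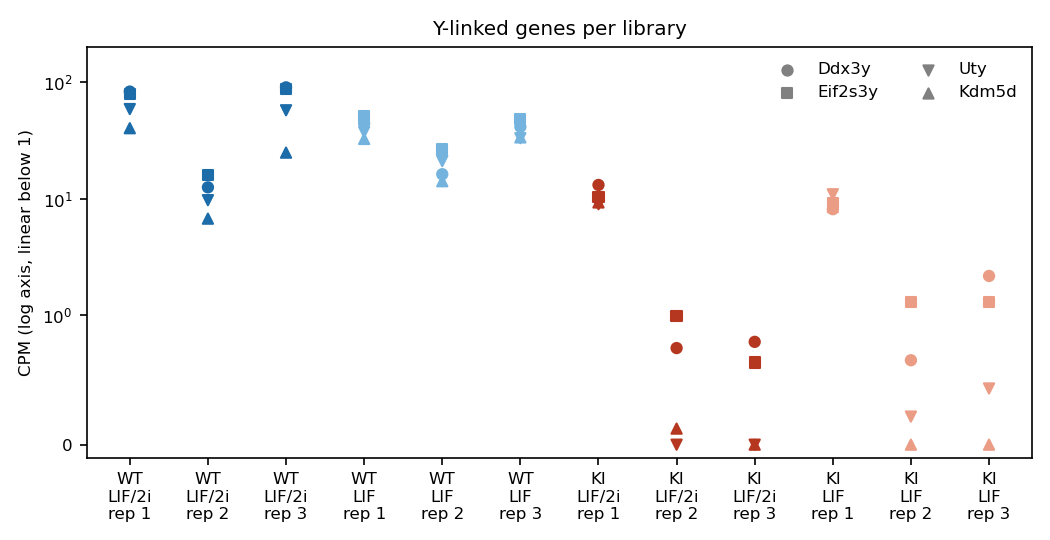
CPM (log axis, linear below 1) of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d in each of the 12 libraries, coloured by group. KI replicate 1 lies above KI replicates 2 and 3 in both media, and WT LIF/2i replicate 2, with a sum of 44.9 CPM, lies below the other WT libraries in that medium.

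In LIF/2i, the comparison of KI with WT asked what the mutation changes where naive pluripotency is held by both inhibitors. Myo7a, an unconventional myosin, fell from 73.3 ± 10.5 CPM in WT to 2.59 ± 1.19 in KI (SD, n = 3 each), a log2 fold change of -4.86 ± 0.31 (SE, adjusted p = 2.77e-05). Naalad2, a glutamate-releasing peptidase, fell from 43.9 ± 4.36 to 2.1 ± 0.986 CPM (log2 -4.33 ± 0.34, adjusted p = 9.52e-05). Lin28a, an RNA-binding protein of pluripotent cells that blocks let-7 maturation, rose from 5.95 ± 0.441 to 53.5 ± 25.7 CPM (log2 3.17 ± 0.39, adjusted p = 0.00269). Ccnd1, encoding cyclin D1, rose from 14.1 ± 7.15 to 85.4 ± 28.8 CPM (log2 2.59 ± 0.32, adjusted p = 0.00332). The naive pluripotency list showed no such shift, with 0 of 20 members called by edgeR over all genes and 0 adjusted over the list alone, and a median log2 fold change of 0.07 (adjusted p = 0.942).

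Genes past the threshold in LIF/2i numbered 129 higher and 165 lower of 13239 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), of which 94 and 123 changed over 2-fold. Myo1f rose from 1.07 to 29 CPM (log2 4.94 ± 0.49, adjusted p = 0.000607), and Spry4, a feedback inhibitor of ERK signalling, from 1.29 to 14 CPM (3.23 ± 0.51, adjusted p = 0.0102). Lrrn2, Heph and Rragb also rose, to 9.27, 16.2 and 21.1 CPM from 0.748, 1.53 and 2.07. Lower genes included Slc16a3, a lactate exporter (140 ± 145 to 9.83 ± 5.84 CPM), Ccdc170 (11.9 to 1.22), Rnf43, a Wnt-induced ubiquitin ligase that removes Wnt receptors (10 to 1.09), and Pdzrn4 (9.22 to 1.12). Nanog, Esrrb, Klf4, Pou5f1, Dnmt3b and Atf4 were not called, with log2 fold changes of 0.36, 0.33, 0.06, 0.12, -0.04 and 0.43. Asns and Trib3, targets of Atf4, were not called either, at -0.16 ± 0.24 and 0.34 ± 0.29. The list of Atf4 targets had a median of -0.17 (adjusted p = 0.307), with 1 of 38 rising over all genes, the amino acid transporter Slc7a3, and 1 rising and 1 falling adjusted over the list alone.

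Of the 29 lists tested, 7 were called in LIF/2i by camera with a preset correlation and 0 with an estimated one. The p53 targets had 23 of 23 members below 0 with a median of -0.62 and none called over all genes or adjusted over the list alone (list adjusted p = 6.06e-06, and adjusted p = 0.898 with an estimated correlation). They moved with the libraries: relative to the WT LIF/2i mean the list median was -0.16 in KI replicate 1, against -1.26 and -0.63 in replicates 2 and 3. Of 22 glycolysis genes 3 fell (Slc16a3, Aldoc and the glucose transporter Slc2a1), and 12 fell and 1 rose adjusted over the list alone, with a median of -0.61 (adjusted p = 6.06e-06, and adjusted p = 0.898 with an estimated correlation). WT replicate 2, the library low in Y-linked transcripts, had a glycolysis median of -0.67, as low as the KI libraries (-0.55, -0.66 and -0.70), against 0.02 and 0.61 in WT replicates 1 and 3. Slc16a3 stood at 102, 18.8 and 300 CPM in the WT libraries. Without WT LIF/2i replicate 3 neither Slc16a3 nor Aldoc was called (log2 -2.58 and -1.47, adjusted p = 0.0747 and 0.056).

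ERK target genes had a median of 0.33, and 2 of 20 rose, Ccnd1 and Spry4, with 6 rising adjusted over the list alone (list adjusted p = 0.000638, and adjusted p = 0.557 with an estimated correlation). Primitive endoderm markers had a median of -0.73 with 0 of 17 called, over all genes or adjusted over the list alone (adjusted p = 0.00133, and adjusted p = 0.557 with an estimated correlation). Relative to the WT LIF/2i mean, WT replicate 2 had a primitive endoderm median of -0.43, near KI replicate 1 at -0.50. WT replicates 1 and 3 stood at 0.04 and 0.46, and KI replicates 2 and 3 at -0.77 and -0.81. Nuclear genes of oxidative phosphorylation lay above 0 for 60 of 75 members with a median of 0.15 (adjusted p = 0.0107), although the called member, Ndufv3, a complex I subunit, fell by 0.73 on the log2 scale, alone over all genes and adjusted over the list alone. Lysosomal genes had a median of -0.19 (adjusted p = 0.012), and 1 of 34 fell, Psap, the saposin precursor, or 2 adjusted over the list alone. Fibroblast markers had a median of 1.11 with 0 of 14 called, over all genes or adjusted over the list alone (adjusted p = 0.0371). These last 3 lists each had adjusted p = 0.898 with an estimated correlation. The oxidative phosphorylation call was lost without WT LIF/2i replicate 3 (adjusted p = 0.315) or KI LIF/2i replicate 1 (0.0965), and the lysosomal call without WT replicate 2 (0.0612) or KI replicate 1 (0.0562). The fibroblast call was lost without WT replicate 2 (0.161) or KI replicate 2 (0.0536) or 3 (0.102).

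The counts in LIF/2i depended on single libraries. Without KI replicate 1 they became 474 higher and 527 lower, and without KI replicate 2 or 3 they became 68 and 66 or 48 and 32. Without WT replicate 1, 2 or 3 they were 31 and 33, 37 and 67, or 82 and 76. Myo7a, Naalad2, Lin28a, Ccnd1, Myo1f and Ccdc170 were called whichever library was left out. Spry4 was not called without WT replicate 1 (adjusted p = 0.057), nor Rnf43 without WT replicate 1 or 2 (0.065 and 0.0502). Heph, Rragb and Psap were lost without WT replicate 1, 2 or 3 or KI replicate 2 or 3, and Pdzrn4 without WT replicate 1, 2 or 3 or KI replicate 2. Lrrn2, Ndufv3, Slc16a3 and Aldoc were lost without WT replicate 1 or 3 or KI replicate 2 or 3.

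**Figure D2:**
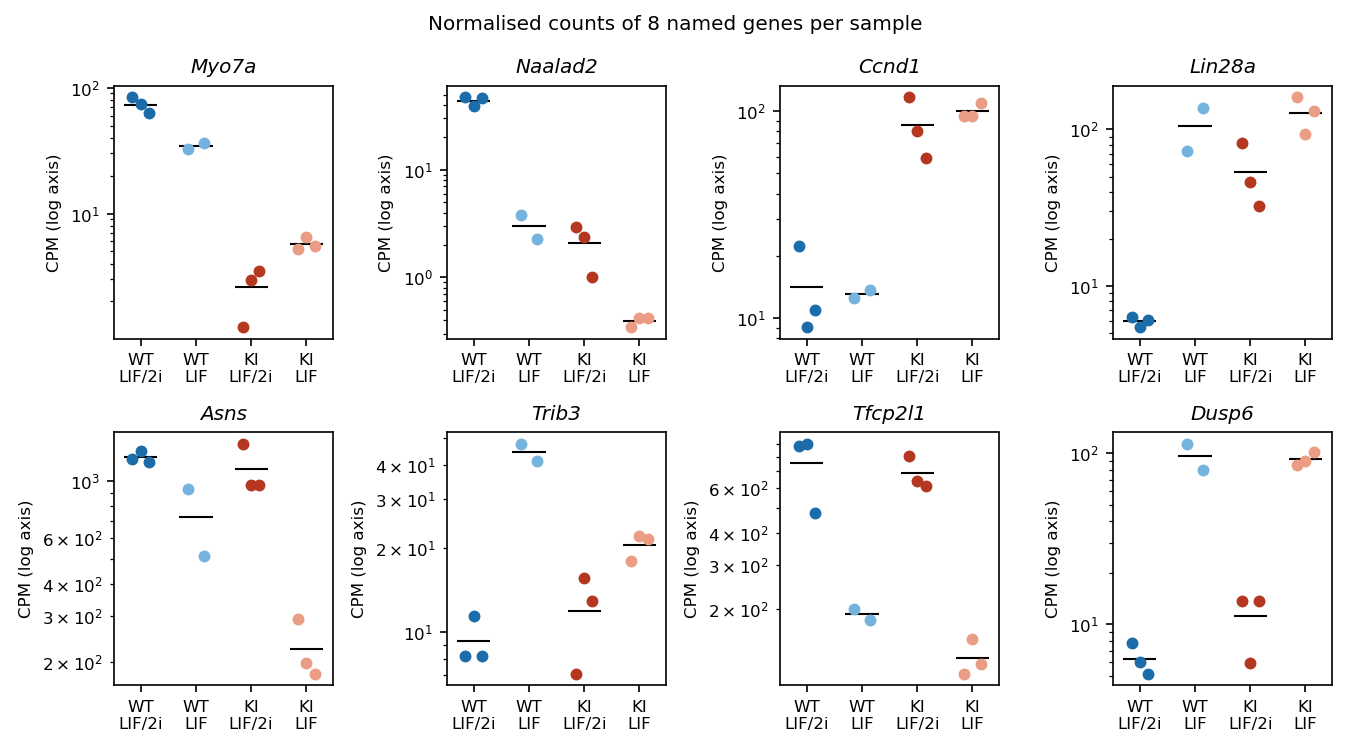
Normalised counts (CPM, log axis) of 8 named genes in the 11 samples, with 1 point per sample and a horizontal line at each group mean; n = 3 per group except WT LIF, n = 2. Myo7a and Naalad2 were lower and Ccnd1 and Lin28a higher in KI than WT in LIF/2i, Asns was lower in KI than WT in LIF, and Dusp6 rose and Tfcp2l1 fell from LIF/2i to LIF in both genotypes.

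In LIF alone, KI and WT cells were compared where ERK and GSK3 signalling are uninhibited. Targets of Atf4 were lower in KI cells as a group: 34 of 38 lay below 0, the median log2 fold change was -0.86 (camera adjusted p = 4.35e-22), and the call held with an estimated correlation (adjusted p = 0.0186). Over all genes 4 members fell and 0 rose, and 18 fell and 0 rose adjusted over the list alone. Asns, asparagine synthetase (chromosome 6, 7675169 to 7692871), fell from 723 ± 296 CPM (SD, n = 2) to 223 ± 60.4 (SD, n = 3), a log2 fold change of -1.69 ± 0.26 (SE, adjusted p = 0.0313). Pck2, mitochondrial phosphoenolpyruvate carboxykinase, fell from 107 ± 1.18 to 30.6 ± 4.22 CPM (log2 -1.80 ± 0.22, adjusted p = 0.0101), and the serine synthesis enzymes Psat1 and Psph fell by 1.29 and 1.28 on the log2 scale (adjusted p = 0.0459 and 0.0428). Trib3, a pseudokinase induced by Atf4, was at 44.3 CPM in WT and 20.6 in KI, not past the threshold (log2 -1.10 ± 0.30, adjusted p = 0.205), and Atf4 transcripts were at 389 and 328 CPM (log2 -0.25 ± 0.20, adjusted p = 0.722).

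Primitive endoderm markers were lower in KI cells in LIF, with 17 of 17 below 0 and a median of -1.55 (adjusted p = 2.22e-10, and adjusted p = 0.0294 with an estimated correlation). Lama1, a laminin chain of the basement membrane, fell from 171 to 49.4 CPM (log2 -1.79 ± 0.26, adjusted p = 0.0221). It was the member called of 17 over all genes, and 4 fell adjusted over the list alone. Trophectoderm markers had a median of -1.06 with 0 of 13 called, over all genes or adjusted over the list alone (adjusted p = 0.000235, and adjusted p = 0.19 with an estimated correlation). That call was lost without WT LIF replicate 2 (adjusted p = 0.0948).

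The other lists called in LIF were lost with an estimated correlation. The tRNA synthetases had a median of -0.23 with 0 of 20 called over all genes and 4 lower adjusted over the list alone (adjusted p = 5.64e-05, and adjusted p = 0.381 with an estimated correlation). Without both agreeing WT LIF libraries that list had adjusted p = 0.0517. Lysosomal genes had a median of -0.19, with 0 of 34 called over all genes and 3 lower adjusted over the list alone (adjusted p = 3e-05, and adjusted p = 0.19 with an estimated correlation). Formative and primed markers had a median of 0.49 and core pluripotency genes of 0.30, each with 0 called over all genes and 3 higher adjusted over the list alone (adjusted p = 5.64e-05 and 8.16e-05, and adjusted p = 0.181 for each with an estimated correlation). Nodal and TGFβ targets had a median of 0.61 with 0 of 9 called over all genes and 1 higher adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.19 with an estimated correlation), and adjusted p = 0.076 without the agreeing pair of WT LIF libraries. Wnt targets had a median of 0.44 and 1 of 14 rose, Ccnd1, over all genes and adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.418 with an estimated correlation). Without KI LIF replicate 1 the Wnt list had adjusted p = 0.0529, and without the agreeing pair 0.225. The naive list had a median of 0.08 with 0 of 20 called, over all genes or adjusted over the list alone (adjusted p = 0.782).

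Ribosomal protein genes (median 0.12, 0 of 76 called over all genes or adjusted over the list alone) and mitochondrially encoded genes (median -0.54, 0 of 13 called either way, adjusted over the list alone included) each had adjusted p = 0.0375. With an estimated correlation these became adjusted p = 0.595 and adjusted p = 0.749. The ribosomal call was lost without WT LIF replicate 2 (adjusted p = 0.171), replicate 3 (0.053) or KI LIF replicate 1 (0.17). The mitochondrial call was lost without WT LIF replicate 2 (0.26) or 3 (0.053), or KI LIF replicate 2 (0.0995) or 3 (0.123). With the replicate number as a block over 12 libraries the ribosomal and mitochondrial calls were also lost (adjusted p = 0.0707 and 0.075). Both families have near-identical copies in the genome, so their levels are uncertain.

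Over all genes 2 were higher and 17 lower in KI cells in LIF, all changed over 2-fold. Ccnd1 rose from 13.1 ± 0.82 to 99.8 ± 8.49 CPM (log2 2.93 ± 0.38, adjusted p = 0.0162), and Olig2, a neural transcription factor, from 25.4 to 85.2 CPM (1.75 ± 0.25, adjusted p = 0.0221). Sema5a, a semaphorin, fell from 49.5 to 9.06 CPM (-2.45 ± 0.24, adjusted p = 0.00384), and Myo7a from 34.2 to 5.72 CPM (-2.56 ± 0.32, adjusted p = 0.0101). Aox3, Hesx1, Dnah12 and Rhox6 also fell, from 21.8, 14.9, 32.7 and 19.7 CPM to 3.18, 2.86, 6.74 and 3.37. Rhox6 belongs to a cluster of similar genes and its level is uncertain. Of the panel genes, Nanog (log2 -0.30), Esrrb (0.05), Klf4 (0.57), Pou5f1 (0.49) and Dnmt3b (0.38) were not called. Of the genes named for LIF by the rule, Sema5a alone was called whichever library was left out. Ccnd1, Olig2, Aox3, Myo7a, Rhox6, Hesx1, Dnah12, Pck2, Asns and Lama1 were each lost without KI LIF replicate 2, without KI LIF replicate 3 and without the agreeing WT pair. All of these but Asns and Dnah12 were also lost without WT LIF replicate 2, and Rhox6 without KI LIF replicate 1. Without KI LIF replicate 2 or 3, 0 genes were higher and 1 lower by edgeR, and without KI LIF replicate 1 5 and 17. Without WT LIF replicate 2 the counts were 0 and 7, and without both agreeing WT LIF libraries 0 and 2. With all samples, 1422 genes had an unadjusted p under 0.05, and DESeq2 called 86 higher and 120 lower and limma-voom 2 and 9.

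The genotype effects shared genes between media. Of those called in LIF, 10 were also called in LIF/2i in the same direction: Ccnd1 and Olig2 were higher, where 0.0195 shared genes are expected of independent lists, and Myo7a, Dhrs7, Sgpp1, Aox3, Sema5a, Dnah12, Med12l and Dclk2 were lower, where 0.212 are expected (Fisher's exact test, one table per direction, p = 9.42e-05 and 1.09e-11). KI replicates 1 and 2 each deviate together with the same number across media. The genotype effects in LIF/2i and LIF are therefore not independent, and these expectations and p-values ignore that pairing. These genes were listed as the whole overlap, after their values were seen. By DESeq2 the overlap was 93 genes, and with all 12 libraries counted separately 48. The log2 fold changes of the genotype in both media had Pearson r = 0.411 across genes, which are not independent replicates, and the pairing of KI samples enters this value too.

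The test of the difference itself, the interaction of genotype and medium, called 0 genes higher and 0 lower by edgeR. At an unadjusted p under 0.05 there were 798 genes, and the smallest adjusted p was 0.136. With no difference at all, a share of 0.05 of the 13239 genes tested would lie under that unadjusted threshold. DESeq2 called 9 higher and 13 lower and limma-voom 0. Without KI LIF/2i replicate 1 edgeR called 1 higher and 3 lower, and without both agreeing WT LIF libraries 0 and 1. The Atf4 target list was called in this test, with a median of -0.66, 30 of 38 members below 0, 0 called over all genes and 8 lower adjusted over the list alone (adjusted p = 2.38e-12, and adjusted p = 0.0909 with an estimated correlation). Asns had an interaction log2 fold change of -1.53 ± 0.35 (adjusted p = 0.538) and Trib3 of -1.44 ± 0.42 (adjusted p = 0.708), while Nanog, Esrrb, Klf4, Pou5f1, Dnmt3b, Atf4 and Eif2s1 had -0.66, -0.28, 0.51, 0.38, 0.41, -0.67 and -0.50, none called. The plot of list medians shows the pattern per sample: relative to the WT LIF/2i mean, Atf4 targets stood at 0.92 and 0.57 in WT LIF and at -0.07, -0.00 and -0.15 in KI LIF.

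**Figure D3:**
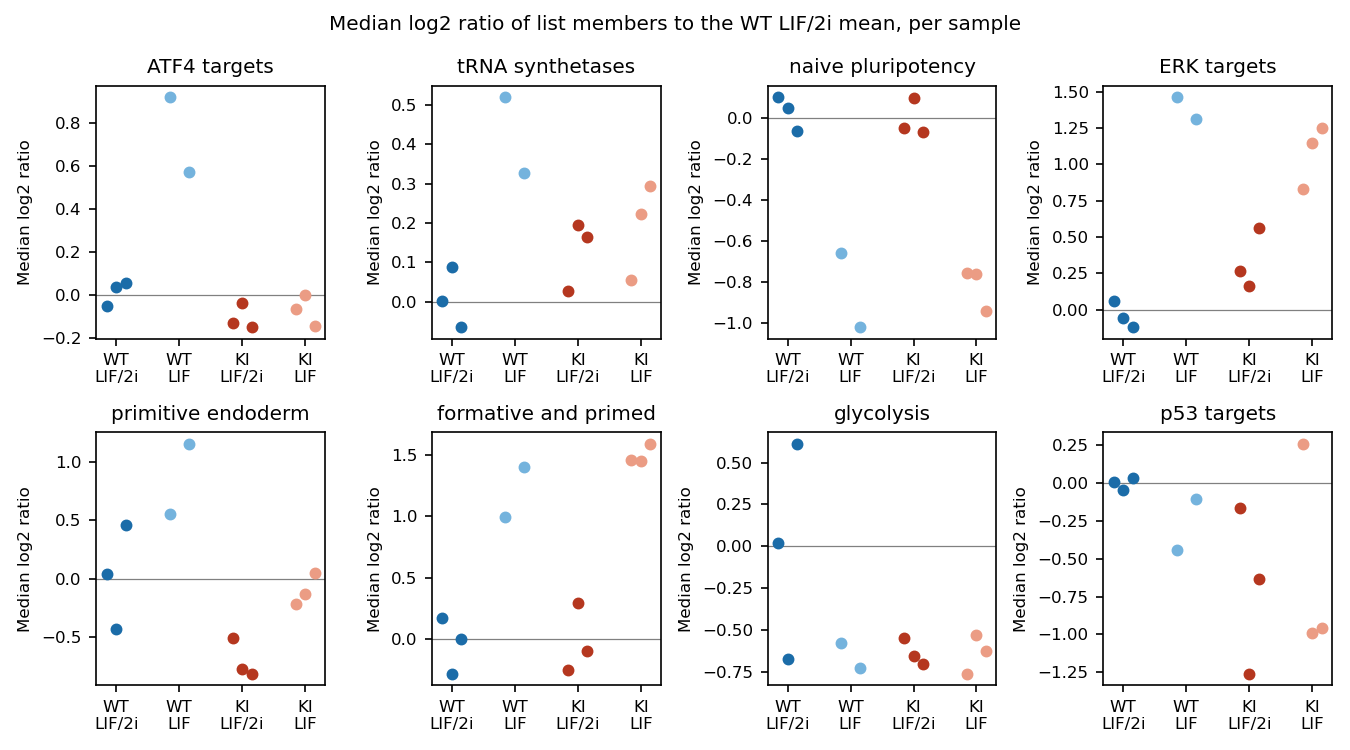
Median log2 ratio of the members of 8 gene lists to the WT LIF/2i mean, 1 point per sample, for the 4 groups (n = 3, WT LIF n = 2). ATF4 targets were raised in the WT LIF samples (0.92 and 0.57) and not in the KI LIF samples, while naive pluripotency genes lay below 0 in every LIF sample of both genotypes.

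Removal of the inhibitors was compared within each genotype to ask how the exit from the LIF/2i state appears in WT and KI cells. In WT cells, ERK targets rose in LIF: 9 of 20 rose and 0 fell, 14 rose adjusted over the list alone, and the median was 1.55 (adjusted p = 4.62e-12, and adjusted p = 0.0388 with an estimated correlation). Dusp6, an ERK phosphatase (chromosome 10, 99263231 to 99267488), rose from 6.3 ± 1.31 CPM (SD, n = 3) to 96.4 ± 23.4 (SD, n = 2), a log2 fold change of 3.91 ± 0.32 (SE, adjusted p = 9.35e-05), and Spry4 rose from 1.29 to 68.7 CPM (5.53 ± 0.52, adjusted p = 0.000225). Naive pluripotency genes fell: 12 of 20 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.84 (adjusted p = 2.7e-10, and adjusted p = 0.0388 with an estimated correlation). Prdm14 fell from 104 to 20.8 CPM (-2.32 ± 0.29, adjusted p = 0.000835) and Tfcp2l1 from 753 to 191 CPM (-1.98 ± 0.26, adjusted p = 0.00113). Nanog fell by 0.66 and Klf4 by 0.93 on the log2 scale (adjusted p = 0.0161 and 0.00638), while Esrrb at -0.39 and Pou5f1 at -0.26 were not called. Without WT LIF replicate 2 neither Nanog nor Klf4 was called (adjusted p = 0.155 and 0.0972), and Nanog was also lost without the agreeing pair (0.0654).

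Of 38 Atf4 targets 14 rose and 0 fell in WT cells in LIF, and 19 rose and 1 fell adjusted over the list alone, with a median of 0.77 (adjusted p = 4.95e-07, and adjusted p = 0.159 with an estimated correlation). Psat1 rose from 76.2 to 242 CPM (1.67 ± 0.22, adjusted p = 0.000962), Trib3 from 9.3 to 44.3 CPM (2.24 ± 0.31, adjusted p = 0.00126) and Atf4 from 243 to 389 CPM (0.68 ± 0.20, adjusted p = 0.0429). The call of Atf4 was lost without WT LIF/2i replicate 1, 2 or 3, WT LIF replicate 2 or the agreeing pair (adjusted p = 0.0847 to 0.175). Asns went the other way without being called (1230 to 723 CPM, -0.77 ± 0.27, adjusted p = 0.0819), at 932 CPM in the agreeing pair and 513 in WT LIF replicate 2, and was called lower without the pair (adjusted p = 0.0339). The tRNA synthetases followed, with 7 of 20 rising and 0 falling, 10 rising adjusted over the list alone and a median of 0.40 (adjusted p = 3.69e-05, and adjusted p = 0.313 with an estimated correlation). Nars and Sars rose by 1.06 ± 0.15 and 1.14 ± 0.19 (adjusted p = 0.0017 and 0.00324).

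Wnt targets fell after removal of both inhibitors, with 7 of 14 lower and 0 higher over all genes. Adjusted over the list alone 7 were lower and 1 higher, and the median was -1.26 (adjusted p = 0.000116, and adjusted p = 0.248 with an estimated correlation). The comparison does not separate the GSK3 inhibitor from the MEK inhibitor. Tnfrsf19 fell from 43 to 8.45 CPM (-2.34 ± 0.31, adjusted p = 0.00106), Cdx1 from 97.1 to 4.74 CPM (-4.37 ± 0.86, adjusted p = 0.00723) and Sp5 from 26.9 to 0.303 CPM (adjusted p = 0.00734). Cdx1 and Sp5 were lost without WT LIF replicate 2 (adjusted p = 0.0899 and 0.0512) or the agreeing pair (0.0509 and 0.0664). Of 22 imprinted genes 9 rose and 2 fell, and 12 rose and 2 fell adjusted over the list alone (median 1.17, adjusted p = 0.000325, and adjusted p = 0.248 with an estimated correlation). Mest rose from 29.2 to 255 CPM (3.13 ± 0.26, adjusted p = 9.35e-05), while Plagl1 fell from 234 to 12.7 CPM (-4.20 ± 0.42, adjusted p = 0.000247).

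Some lists of lineage markers were called higher in WT LIF with a preset correlation, where the libraries differed, and each was lost with an estimated one. Formative and primed markers had a median of 1.22, with 6 of 19 rising and 1 falling, or 11 and 2 adjusted over the list alone (adjusted p = 0.00453, and adjusted p = 0.313 with an estimated correlation), and Dnmt3b, a de novo DNA methyltransferase, rose from 129 to 268 CPM (1.06 ± 0.22, adjusted p = 0.00916), a call lost without WT LIF replicate 2 (adjusted p = 0.104). Fibroblast markers had a median of 1.82, with 7 of 14 rising and 1 falling, or 8 and 1 adjusted over the list alone (adjusted p = 0.00453, and adjusted p = 0.435 with an estimated correlation). WT LIF replicate 2 held 206 CPM of Col1a2, 95.1 of Tagln and 8.34 of the immediate early gene Egr1, against 7.43, 20.9 and 209 CPM in the agreeing pair. Trophectoderm markers had a median of 1.71, with 6 of 13 rising and 2 falling, or 7 and 2 adjusted over the list alone (adjusted p = 0.00389, and adjusted p = 0.313 with an estimated correlation). Primitive endoderm markers had a median of 0.85, with 3 of 17 rising and 1 falling, or 6 and 1 adjusted over the list alone (adjusted p = 0.00292, and adjusted p = 0.248 with an estimated correlation). With the agreeing libraries counted separately, the fibroblast and trophectoderm lists had adjusted p = 0.0542 and 0.0516. Neuroectoderm markers (median 0.44, 2 of 9 rising and 0 falling, or 3 and 0 adjusted over the list alone, adjusted p = 0.105) and mesendoderm markers (median -0.21, 1 of 5 rising and 1 falling, over all genes and adjusted over the list alone, adjusted p = 0.748) were not called.

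Lysosomal genes had a median of -0.27, with 9 of 34 falling and 1 rising, or 10 and 1 adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.325 with an estimated correlation). Glycolysis genes had a median of -0.65, with 2 of 22 rising and 2 falling, or 2 and 3 adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.83 with an estimated correlation). That call was lost without WT LIF/2i replicate 3 (adjusted p = 0.517), the library with the highest glycolysis median.

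In total 836 genes were higher and 886 lower in WT LIF than WT LIF/2i, 700 and 589 of them by over 2-fold. Car4, a carbonic anhydrase, was at 58.4 CPM in LIF and 0.101 in LIF/2i (adjusted p = 0.000247), Bmp4 at 33.4 and 0.441 (adjusted p = 0.000573) and Arap3 at 26.1 and 0.543 (adjusted p = 0.000492). Stk33, Trpm1, Hoxc12, Srarp and Gpld1 fell from 29.1, 32.3, 9.3, 11.3 and 15.2 CPM to 0.155, 0.382, 0.158, 0.234 and 0.385. Several of these levels lie under 3 counts per library, so no fold is given for them. Stk33 and Srarp were lost without WT LIF replicate 2, and Srarp also without the agreeing pair. Without WT LIF replicate 2 the counts were 204 higher and 195 lower, without the agreeing pair 439 and 327, and without WT LIF/2i replicate 1 380 and 465 and replicate 2 440 and 614.

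In KI cells, removal of the inhibitors lowered the same list of naive genes: 12 of 20 fell and 0 rose, 16 fell and 1 rose adjusted over the list alone, and the median was -0.89 (adjusted p = 1.72e-14, and adjusted p = 0.0192 with an estimated correlation). Tfcp2l1 fell from 687 ± 103 to 129 ± 21.4 CPM (SD, n = 3 each), a log2 fold change of -2.41 ± 0.23 (SE, adjusted p = 0.000318), and Nanog from 630 to 252 CPM (-1.32 ± 0.14, adjusted p = 0.000428). Formative and primed markers rose in 8 of 19 and fell in 0, or 13 and 0 adjusted over the list alone, with a median of 1.52 (adjusted p = 1.65e-11, and adjusted p = 0.0192 with an estimated correlation). Pou3f1, a transcription factor of epiblast and neural cells, rose from 2.07 to 49.9 CPM (4.56 ± 0.59, adjusted p = 0.000974), Dnmt3a from 107 to 528 CPM (adjusted p = 0.000922) and Dnmt3b by 1.47 ± 0.20 (adjusted p = 0.00138). ERK targets rose in 5 of 20 and fell in 0, or 7 and 0 adjusted over the list alone, with a median of 0.93 (adjusted p = 4.59e-08, and adjusted p = 0.0678 with an estimated correlation). Dusp6 rose from 11.2 to 92.3 CPM (3.05 ± 0.29, adjusted p = 0.000296) and Dusp4 from 2.04 to 11.8 CPM (2.56 ± 0.38, adjusted p = 0.00217).

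The Atf4 target list differed from that in WT cells by the interaction test with a preset correlation (adjusted p = 2.38e-12), a call lost with an estimated one (adjusted p = 0.0909 with an estimated correlation). In KI cells 1 Atf4 target rose and 2 fell of 38, or 1 and 1 adjusted over the list alone, and the median was 0.10 (adjusted p = 0.851). Asns fell from 1100 ± 244 to 223 ± 60.4 CPM (-2.31 ± 0.25, adjusted p = 0.000469), while Trib3 (0.80 ± 0.28, adjusted p = 0.106) and Atf4 (0.00 ± 0.18, adjusted p = 0.998) were not called. With the replicate number as a block within KI cells, Trib3 was called (log2 0.84). The tRNA synthetases had 0 of 20 called, over all genes or adjusted over the list alone, and a median of 0.07 (adjusted p = 0.746).

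Lysosomal genes had a median of -0.37 in KI cells, with 9 of 34 falling and 0 rising, or 17 and 1 adjusted over the list alone (adjusted p = 3.21e-06, and adjusted p = 0.195 with an estimated correlation). Glb1 and Ctsc, a lysosomal galactosidase and a cathepsin, fell by 1.08 and 2.96 on the log2 scale (adjusted p = 0.00139 and 0.00227). Imprinted genes rose in 7 of 22 and fell in 1, or 11 and 2 adjusted over the list alone (median 1.06, adjusted p = 0.000264, and adjusted p = 0.195 with an estimated correlation), with Mest at 105 and 331 CPM (1.66 ± 0.23, adjusted p = 0.00129) and Plagl1 at 153 and 10.1 CPM (-3.91 ± 0.37, adjusted p = 0.000296). Fibroblast markers had a median of 1.87, with 4 of 14 rising and 1 falling, or 7 and 1 adjusted over the list alone (adjusted p = 0.000938, and adjusted p = 0.54 with an estimated correlation). Acta2 rose from 6.12 to 51.5 CPM (3.10 ± 0.63, adjusted p = 0.0108), while Fn1, the most abundant member, fell from 4020 to 1950 CPM (-1.04 ± 0.16, adjusted p = 0.00223). Neuroectoderm markers had a median of 0.59, with 3 of 9 rising, among them Sox1 and Pax6, and 0 falling, over all genes and adjusted over the list alone (adjusted p = 0.0233, and adjusted p = 0.195 with an estimated correlation). That call was lost without KI LIF/2i replicate 1 (adjusted p = 0.127).

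In all, 536 genes were higher and 663 lower in KI LIF than KI LIF/2i, 460 and 392 of them by over 2-fold. Car4, Col1a2, Neurod1, Wt1 and Insm1 were higher, at 50.1, 40, 10.5, 30.4 and 14.3 CPM in LIF against 0.425, 1.16, 0.299, 1.03 and 0.501 in LIF/2i. Trpm1, Hoxc12, Stk33, Sh2d4b and Ddr2 were lower, at 0.491, 0.396, 0.647, 0.786 and 0.742 CPM in LIF against 15.4, 11.4, 15.1, 18.6 and 10.8. Esrrb fell by 0.67 on the log2 scale (adjusted p = 0.0175), a call lost without KI LIF/2i replicate 1 (0.0561) or KI LIF replicate 2 (0.0823) or 3 (0.0913). Stk33 was lost without KI LIF replicate 2 or 3, and Klf4 at -0.42 and Pou5f1 at 0.12 were not called. The replicate numbers match KI replicates 1 and 2 across media, and replicate 3 hardly. With the replicate number as a block within KI cells the counts were 831 higher and 963 lower, and Col1a2 was no longer called. Without KI LIF replicate 2 or 3 they were 214 and 351 or 209 and 283.

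The medium effects in WT and KI cells shared 334 higher genes, where 33.8 are expected of independent lists, and 431 lower genes, where 44.4 are expected, with 1 gene called in opposite directions. Across genes their log2 fold changes had Pearson r = 0.752.

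**Figure D4:**
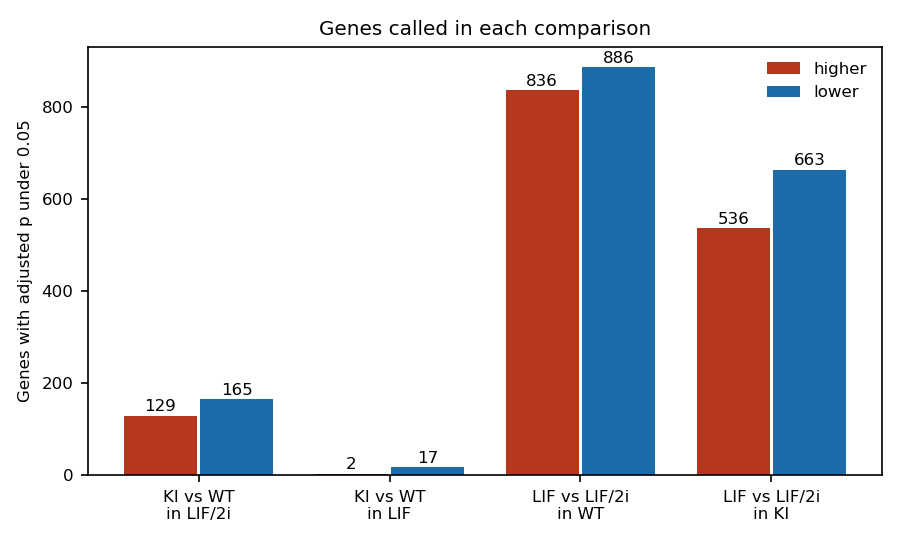
Number of genes with an adjusted p under 0.05 (edgeR) that were higher (red) or lower (blue) in each comparison, from 13239 genes tested. Between media 1722 genes were called in WT cells and 1199 in KI cells, and between genotypes 294 in LIF/2i and 19 in LIF. These counts are not sizes of effect, since depth and sample number differed between the groups. The interaction of genotype and medium called 0 genes.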

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

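The tests of depth and of GC content with coding length were set before their results were seen; leaving out each library was planned, but its use as a test of the first pattern, the setting without both agreeing libraries, and the tests of mixed cells, of X and Y dosage and of other splits of the samples were chosen only after the results were seen.

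The genotype effect differed between LIF and LIF/2i for 11 lists by the camera test of the interaction with a preset correlation, and for none with an estimated correlation, where the smallest adjusted p was 0.0909. The differences (LIF minus LIF/2i) were lower for ATF4 targets (adjusted p = 2.38e-12), tRNA synthetases (median -0.44, adjusted p = 7.44e-08), ERK targets (-0.38, 0.000146), mitochondrially encoded genes (-0.89, 0.00419), oxidative phosphorylation (-0.15, 0.00486) and trophectoderm markers (-1.41, 0.00723). They were higher for formative and primed markers (median 0.37, adjusted p = 6.47e-05), Wnt targets (0.56, 0.000102), glycolysis (0.60, 0.00024), p53 targets (0.36, 0.000853) and Nodal and TGFβ targets (0.60, 0.00669). The glycolysis and oxidative phosphorylation differences were lost without WT LIF/2i replicate 3 (0.109 and 0.243), and the p53 difference without KI LIF/2i replicate 2 (0.0791) or KI LIF replicate 1 (0.681). The mitochondrial difference was lost without WT LIF/2i replicate 3 (0.109), WT LIF replicate 2 (0.0842) or KI LIF/2i replicate 3 (0.275). The trophectoderm difference was lost without WT LIF/2i replicate 2 (0.0877) or WT LIF replicate 2 (0.173), and the Nodal difference without WT LIF/2i replicate 1 (0.0607) or without the agreeing pair of WT LIF libraries (0.0933).

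The first pattern weighed was the lower level of ATF4 targets in KI than WT in LIF. With every sample thinned to the total of the shallowest, the list median stayed between -0.981 and -0.768 over 20 draws (SD 0.0565). Thinning leaves the expected ratios of well-counted genes unchanged. The draws therefore argue only against unequal depth acting through low counts as the whole cause. A trend with GC content and coding length was removed for 38 of 38 members and left a median of -0.847 ± 0.143 (SE), and over the libraries left out the highest adjusted p was 3.38e-11, without both agreeing WT LIF libraries. The SE of the median after the trend came from resampling list members and not samples. That trend spanned only -0.102 to 0.0817 on the log2 scale (10th to 90th percentile over genes), so its removal could move the list little. Libraries were left out with the preset correlation only, so how the list would stand without them under an estimated correlation was not tested. Leaving out both agreeing libraries also left 1 sample in WT LIF, whose spread was assumed. A loss of eIF2α phosphorylation is a candidate explanation that the design names, as a hypothesis, which return of a phosphorylatable eIF2α to the KI cells would test. A difference between the WT and KI lines other than the mutation was not tested and stays open.

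The second pattern was KI replicate 1, which differed from KI replicates 2 and 3 in both media in Y-linked transcripts and p53 targets (list medians -0.16 and 0.26, against -1.26, -0.63, -0.99 and -0.96). WT cells mixed into the KI replicate 1 cultures may account for part of this, and 2 tests were run, in this order: 36 non-Y genes far below WT in replicates 2 and 3 stood at a median of 27.7% of the WT level (95% bootstrap interval 11.9 to 45.8%) in LIF/2i, which holds the Y-linked share of 21.2%, but 11 of the 36 lay under 0.5 times that share and 14 above 2 times it, from -2.86% for Myo7a to 274% for A2m, so the median decides little; in LIF 10 genes stood at 7.92% (-4.64 to 29.5%) with a Y-linked share of 29.2%. A second test, chosen after that result, found 1 of the 36 genes, Myo7a, below 0.5 times the lowest level a mixture allows (1.25 against 9.56 CPM), too few to decide, so a WT admixture is not excluded. Loss of the Y chromosome from part of the cells was tested on WT LIF/2i replicate 2, where the Y-linked genes stood at 14.7 to 20.7% of the other WT libraries (highest to lowest ratio 1.41, under the limit of 2), while in KI replicate 1 they ranged from 12.3 to 28.1% in LIF/2i (ratio 2.29) and from 18.6 to 31.1% of the agreeing pair in LIF (1.67, from 23 to 31 counts a gene), and in WT LIF replicate 2 from 37.3 to 59% (1.58), so it stays open. Female cells with a second active X chromosome are argued against for replicates 2 and 3. There the X minus autosome median was at most 0.142 ± 0.0516 on the log2 scale, with an SE from resampling X-linked genes and not samples.

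For the genes called between KI and WT in LIF/2i, the real split of the 6 samples called 294 and the highest other split 5, with 1 of 10 splits reaching the real count. For the medium in KI cells the real split called 1199 and the highest other 0, again 1 of 10. These splits exchange samples without regard to the pairing of KI replicates 1 and 2 across media. With 10 splits a share under 0.05 cannot be reached.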

How the results depend on the processing

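Directions of the called genes named in the report by rule held under every alternative run on them, while counts moved and some of their calls ended. Over all comparisons limma-voom ended 14 calls of named genes and the test against a 1.5-fold change 18. Only the groups compared ended 9, no filter 2 and library totals alone 1. Of the 19 genes called for KI against WT in LIF, limma-voom kept 9. The counts of KI against WT in LIF/2i, 129 higher and 165 lower, became 405 and 511 by DESeq2, 35 and 24 tested against a 1.5-fold change, and 34 and 42 with only the groups compared. With the replicate number as a block over 12 libraries the counts were 250 and 316, and with 12 libraries counted separately and no block 238 and 284. Counts of the block over 12 libraries, here and below, therefore hold both changes at once. With KI replicates 2 and 3 alone the counts were 690 and 880. Leaving out 1 library gave 31 to 474 and 32 to 527. In LIF, 2 higher and 17 lower became 86 and 120 by DESeq2, 5 and 27 without the filter and 1 and 3 against a 1.5-fold change. They became 65 and 109 with the block over 12 libraries, 57 and 85 with 12 libraries and no block, and 168 and 247 with KI replicates 2 and 3 alone. Limma-voom called 9 lower, and only the groups compared 9 higher. Leaving out 1 library gave 0 to 5 and 1 to 17. For the medium in WT, the test against a 1.5-fold change gave 384 and 338, the block 1316 and 1540, 12 libraries 1497 lower, and leaving out 1 library 204 to 889 and 195 to 886. With 12 libraries and no block, 1240 genes were higher for the medium in WT. The larger counts of the fit with the block there cannot be put down to the block alone. For the medium in KI, the 1.5-fold test gave 185 and 197, the block within KI 831 higher, only the groups compared 413 lower, and leaving out 1 library 209 to 503 and 283 to 592. The interaction, 0 and 0, became 9 and 13 by DESeq2, 1 and 1 with the block, 1 higher with 12 libraries, 1 lower with KI replicates 2 and 3 alone, and 0 to 1 and 0 to 3 leaving out 1 library. The 10 genes shared by the genotype effects became 93 by DESeq2, 1 at an adjusted p under 0.01 and 48 with 12 libraries.

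A stricter hypothesis accounts by construction for the lower counts against a 1.5-fold change. Counts without a library depended on which one it was and not on the number of samples alone, and for these and the other alternatives the cause was not tested. Signs turned for panel genes near 0 that were not called: Klf4 in KI against WT in LIF/2i (-0.0852 with KI replicates 2 and 3 alone, -0.0929 to 0.152 leaving out 1 library), Dnmt3b there (-0.2445 to 0.0782) and, in LIF, Esrrb (-0.0739, and -0.0737 to 0.133). For the medium in KI cells, leaving out 1 library gave -0.00345 to 0.19 for Pou5f1 and -0.164 to 0.136 for Atf4, which stood at -0.017 without the filter and -0.0253 with KI replicates 2 and 3 alone.

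Same-numbered KI samples had correlations of 0.22 to 0.5 across media, but replicate 3, at 0.22, also reached 0.21 with another number. In WT cells 1 of 3 pairs passed 0.1 (replicate 2, 0.13), the replicate also lowest in Y-linked transcripts in both media. The block within KI changed 0 of 18 list calls, ended the call of Col1a2 and added that of Trib3, and changed no other call of a named gene. The block over 12 libraries ended the calls of ribosomal protein and mitochondrially encoded genes in KI against WT in LIF (adjusted p = 0.0707 and 0.075). It added 4 calls of named genes, while also counting the agreeing pair separately. KI replicates 2 and 3 alone ended 5 list calls: oxidative phosphorylation and lysosome in LIF/2i (0.0926 and 0.0714), Wnt targets and ribosomal protein genes in LIF (0.0668 and 0.305) and neuroectoderm markers for the medium in KI (0.103). Counting 12 libraries ended fibroblast markers in LIF/2i (0.0684), fibroblast and trophectoderm markers for the medium in WT (0.0542 and 0.0516) and trophectoderm markers in the interaction (0.0524). Of 48 list calls, an estimated correlation ended 42 and fry 30; by fry the ATF4 targets had adjusted p = 0.00346 for KI against WT in LIF, 0.00255 for the medium in WT and 0.0511 for the interaction. DESeq2's size factors and library totals alone ended none, but with totals alone the balance of higher and lower genes turned for the medium, to 959 and 715 in WT and 591 and 540 in KI, and was 140 and 143 for KI against WT in LIF/2i. Low depth limits KI LIF most, where 3 counts are up to 1.3 CPM.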

Other observations

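The tests of shared controls, with the splits of the controls, and of windows around Eif2s1 were chosen after the data were seen; the tests of lists and genes were planned, and the genes named here were picked after their values were seen. Of the 29 lists tested, 10 were called in none of the comparisons, with a lowest adjusted p of 0.0852 and medians between -0.69 and 1.00: BMP and LIF/STAT3 targets, cholesterol synthesis, DNA methylation machinery, eIF2 machinery, ER chaperones, G2/M genes, germline genes, mesendoderm markers and NRF2 targets. Some of their members changed with the medium. Prdm14 fell and Dnmt3a rose in both genotypes, and in KI cells Uhrf1, the partner of the maintenance methyltransferase, fell by 0.83 and Dnmt3l rose by 2.20 on the log2 scale (adjusted p = 0.00326 and 0.0453). Eif2b5, the catalytic subunit of the exchange factor that phosphorylated eIF2α inhibits, fell in LIF by 1.18 ± 0.16 in WT and 1.22 ± 0.14 in KI (SE, adjusted p = 0.0013 and 0.000639). Id1, a BMP target, rose in WT cells by 2.34 (adjusted p = 0.0088).

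Genes called between KI and WT in LIF/2i overlapped those called between LIF and LIF/2i in WT cells: 77 were higher and 102 lower in both, where 8.15 and 11 are expected of independent lists, and 1 was opposite. Both comparisons share the WT LIF/2i libraries. The log2 fold changes had r = 0.568 across genes, against 0.464 ± 0.0171 (SD of 20 draws) for simulated unchanged groups with those controls. The covariance was 0.425 against 0.0947 simulated, a difference of 0.331. In all 6 ways of giving 1 WT LIF/2i library to one comparison and the other 2 to the other, r ranged from 0.192 to 0.551 and the covariance from 0.221 to 0.486, with a mean of 0.371. The single library has no spread of its own and took that of the other groups, so the calls rest on that assumption: 1 to 18 genes were higher and 3 to 22 lower in both. With replicate 3 alone used for the genotype, r was lowest and 15 genes were opposite, against 10 higher and 17 lower in both.

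Genes near Eif2s1 on chromosome 12 were counted in 4 windows, of 5, 10, 20 and 30 Mb on each side, in both media, 8 tests in all. Called genes made up 4.97% of genes within 10 Mb and 2.19% elsewhere in LIF/2i. Fisher's exact test gave p = 0.0273 to 1 over the windows in LIF/2i and p = 0.0219 to 0.0827 in LIF, and the lowest adjusted over the 8 tests was 0.0704, so none passed. Chromosomes 1 and 4 had higher shares of called genes in LIF/2i, 3.86% and 3.64%, than chromosome 12 with 2.9%, as did chromosome X with 3.3%. The shares within 10, 20 and 30 Mb of Eif2s1, 4.97%, 4.3% and 4.32%, lay above these, and that within 5 Mb, 1.67%, below. Windows of equal size on other chromosomes were not counted, so a local effect is neither shown nor excluded. Dhrs7 and Sgpp1, both lower in KI cells in both media, lie 6.22 and 3.15 Mb from Eif2s1. The 8 genes called within 10 Mb in LIF/2i also included L3hypdh and Gpr135, which fell, and Snw1, Riox1, Vash1 and Vrtn, which rose.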
